A study of Mus musculus with 6 samples.

How the data were processed

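The series holds 6 arrays of splenic B cells, 3 from Crebbp-floxed and 3 from Crebbp-deleted mice, all with a Bcl2 transgene. Per the series' design text the 3 samples of a group come from 3 mice. Per the labels' protocols, spleens were dissociated, frozen viably, thawed and washed, B cells were purified with beads against CD43, RNA was extracted with a column kit and it was labelled with biotin for Affymetrix arrays. The deposited table holds 1 intensity per probe set and array. The submitters' processing notes name RMA, which corrects the background, equalises the arrays' quantiles and summarises the probes of a set; its version is not given in the sources used here. RMA usually returns log2 values, but the deposited values run from 2.96 to 17020, so they are read as intensities on a linear scale. They were log2-transformed here and used with no further normalization. Arrays have no read depth; the number of arrays and the signal of dim probe sets limit the precision.

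Genes were named through the platform's annotation. Of 45101 probe sets 34958 had 1 gene symbol, 932 had several and 9211 had none in the table used, and probe sets with several or none were not named. Symbols were looked up by Entrez ID in a RefSeq gene table of the assembly GRCm38.p6, which held the IDs of 34754 of the single-symbol probe sets; 0 symbols changed. The array manufacturer's 64 control probe sets were not tested as genes. Each of 18194 genes was represented by the probe set with the highest mean over all 6 samples, and no filter on dim probe sets was applied. For named genes, probe sets that moved in opposite directions are given in the results.

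Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), as Crebbp-deleted minus Crebbp-floxed, without covariates, and p-values were adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. The probe sets of Crebbp, Ep300 and Bcl2 were also tested singly, in a fit on all probe sets. A permutation of 3 samples against 3 cannot give a p under 0.1, so no permutation test of single genes was made. The 34 gene lists were fixed before the data were examined. Lists with at least 5 measured genes, 33 in all, were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, and members were counted over all genes and adjusted over the list alone. Camera compares a list with all other genes; fry, also run, does not.

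The genes named in the text follow a rule fixed before the data were examined: Crebbp, Ep300 and Bcl2; the 12 genes with the largest rise and the 12 with the largest fall among those with an adjusted p under 0.05 and no overlap between the groups, leaving out predicted genes and clones without an established symbol; and up to 4 members with the smallest p of each list. Alternatives covered normalization again by quantiles or medians, filters on dim genes, other ways to choose or average probe sets, other limma settings, other thresholds, the replicate number as a block, leaving out each sample in turn, and camera with an estimated correlation or fry. The sex of each mouse, which the labels used here do not give, was read from Xist and Y-linked genes, and fits with sex as a term and within each sex, and camera with an estimated correlation without each sample in turn, were added after seeing the data.

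The procedure was tested on simulated data for this comparison, in 20 runs over 18194 genes with 200 changed genes each. It recovered 22.1% of genes changed by 0.5 log2 units, 74.9% of those changed by 1 and 95.8% of those changed by 2, with a mean of 5.21% false calls. A list shifted by 1 log2 unit passed camera in 20 of 20 runs, and over these runs camera also called unshifted lists that share no gene with it 6 times. The simulated genes varied independently of each other, which real genes need not do. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.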

Results

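Gene expression was measured on Affymetrix mouse arrays in B cells taken from the spleens of 6 mice. All of the mice carried a Bcl2 transgene under the Eµ enhancer, which drives expression in B cells. In 3 of them the gene for the histone acetyltransferase Crebbp was flanked by recombination sites (Crebbp-floxed), and in the other 3 it was deleted (Crebbp-deleted). Each mouse gave 1 array with 45101 probe sets, and the comparison asked how B cells that over-express Bcl2 differ when Crebbp is lost. Spleen cells had been frozen alive and thawed, and the B cells were then purified without touching them, by removing cells that carry CD43 on beads. The 6 arrays had near-equal distributions, with median log2 intensities from 4.28 to 4.30, and the number of arrays limits the precision of every value given here. Expression levels are log2 intensities, and differences are Crebbp-deleted minus Crebbp-floxed.

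Crebbp itself was lower in the deleted samples at each of its 4 probe sets, and at each of them all 3 deleted samples lay below all 3 floxed samples. Probe set 1436983_at had intensities of 1056 ± 13.1 in floxed samples and 614 ± 59.1 in deleted samples (SD, n = 3 each). The deleted group stood at 58% of the floxed group there, a log2 difference of −0.79 ± 0.10 (SE) with a limma adjusted p of 0.033 when all probe sets were tested. Probe set 1435224_at stood at 70.6% of the floxed level (log2 difference −0.50, adjusted p = 0.105), 1434633_at at 69.4% (−0.53, adjusted p = 0.082) and 1459804_at at 51% (−0.97, adjusted p = 0.081). The gene's representative in the test of 1 probe set per gene was 1435224_at, which has the highest mean, and its log2 difference of −0.50 did not pass there (limma adjusted p = 0.078). With the mean of the 4 probe sets in its place the difference was −0.70 and passed (limma adjusted p = 0.039). Where these probe sets lie relative to the deleted part of the gene was not analysed here, so the remaining signal does not measure how much of the gene was left. With the sex of the mice as a term the difference at 1435224_at was −0.53, within males −0.57 and within females −0.50, none of them past the threshold.

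**Figure D1:**
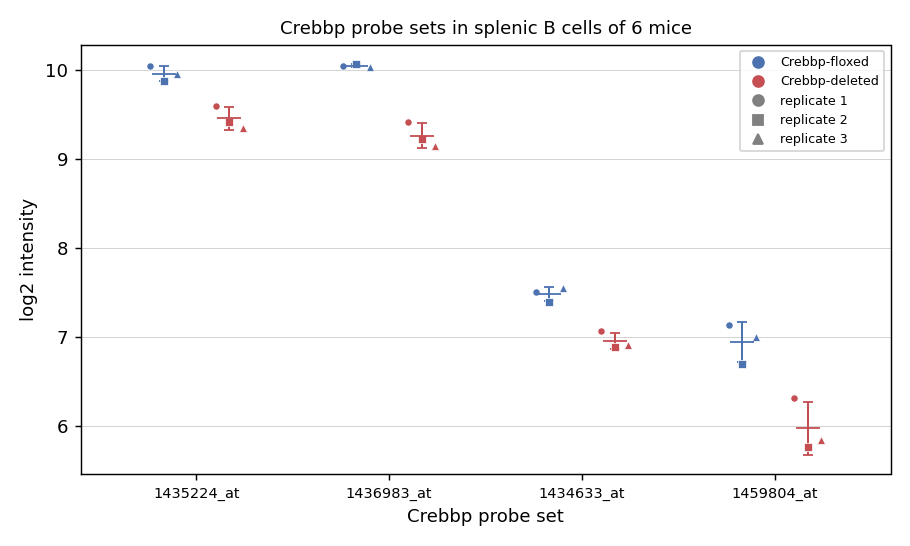
Log2 intensity of the 4 Crebbp probe sets in each of the 6 mice (points), with the mean (horizontal line) and SD (error bar) of the 3 floxed and the 3 deleted samples. All deleted samples lie below all floxed samples at every probe set, and the difference runs from −0.50 to −0.97 on the log2 scale.

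The Crebbp paralog Ep300 did not pass the test, with a log2 difference of 0.26 ± 0.14 (SE, limma adjusted p = 0.433). Bcl2 had probe sets that differed in direction. Its representative, 1457687_at, had a log2 difference of −0.74 ± 0.13 (SE, limma adjusted p = 0.055), and 4 of its 5 probe sets were lower in the deleted samples. Of these 1437122_at passed when all probe sets were tested (−0.85, limma adjusted p = 0.031), while 1422938_at stood 0.43 higher without passing (limma adjusted p = 0.359). Whether any of these probe sets reads the transgene was not analysed here.

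Across the genome, 142 of 18194 genes differed between the groups, 99 higher and 43 lower in the Crebbp-deleted samples (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 59 rose and 23 fell by at least 1 log2 unit. At an unadjusted p under 0.05 limma had 2692 of the 18194 genes, and such counts in the gene lists below are to be read against that share. In all 142 genes the 3 deleted samples lay on one side of the 3 floxed samples, and over all genes 21.2% were separated in this way, where chance gives 10%. The count depended on single mice. Without floxed sample 1 limma called 0 genes, with 1990 at an unadjusted p under 0.05 (2692 with all samples), and without deleted samples 1, 2 and 3 it called 16, 45 and 62, while without floxed sample 3 it called 226. The sexes were unequal between the groups: Xist and the Y-linked genes on each array marked floxed sample 1 and deleted samples 1 and 3 as male and the other 3 as female. With sex as a term 37 genes passed, 34 of them among the 142. Fits within males and within females kept the sign of the difference in all 142 genes, but no other sign was possible, because the groups of these genes do not overlap. Those fits set 1 floxed male against 2 deleted males and 2 floxed females against 1 deleted female, and the lone sample is assumed to vary like the others.

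Among genes past the test that have an established symbol, the largest rise was that of Tjp1, the tight junction scaffold ZO-1. It went from 2.48 ± 0.35 to 6.16 ± 0.49 (SD, n = 3 each), a 12.8-fold increase with a limma adjusted p of 0.0054. The small heat shock protein Hspb1 rose 9.67-fold, the DnaJ co-chaperone Dnaja4 rose 9.25-fold, the Hsp70 co-chaperone Bag3 rose 6.97-fold and the stress-induced transcription factor Atf3 rose 5.04-fold. The membrane glycoprotein Gpm6a rose 7.25-fold, the actin-bundling protein Pls3 rose 6.08-fold, the adhesion receptor Adgrl2 rose 5.65-fold, the magnesium transporter Nipa1 rose 5.42-fold and the Src family kinase Yes1 rose 4.06-fold. The carboxypeptidase Cpq rose 6.34-fold and Prg2, the eosinophil major basic protein, rose 5.20-fold. Adjusted p-values of these 12 genes ran from 0.0054 to 0.045. Cpq and Adgrl2 each had 1 probe set of 3 that went the other way, and 8 of the 12 (all but Hspb1, Bag3, Adgrl2 and Atf3) started from floxed means below the median of all probe set means, 4.29. No detection call was used here, so the size of the folds of these 8 genes, that of Tjp1 included, and their order are uncertain.

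Among genes past the test that have an established symbol, the largest fall was that of Sit1, a transmembrane adaptor that binds the phosphatase SHP2. It went from 5.92 ± 0.15 to 4.02 ± 0.18 (SD, n = 3 each), which is 3.72-fold lower with a limma adjusted p of 0.0054. The RNA helicase Ddx25 was 3.23-fold lower, the acyltransferase of triglyceride synthesis Gpat3 3.17-fold lower and Sox4, a transcription factor that early B cell development requires, 2.56-fold lower. Tlr7, the endosomal receptor for single-stranded RNA, was 2.47-fold lower and Pglyrp2, which hydrolyses peptidoglycan, 2.37-fold lower. The other 6 genes were Tmem108 at 2.49-fold, the LIM domain protein Csrp2 at 2.46-fold, the ubiquitin ligase Rnf157 at 2.31-fold, Ttc30a1, a gene of intraflagellar transport, at 2.28-fold, the tetraspanin Tspan2 at 2.28-fold and the ceramide synthase Cers4 at 2.22-fold, all lower in the deleted samples. The adjusted p-values of these 12 genes ran from 0.0054 to 0.048. The 8 probe sets of Sox4 were divided, with 5 lower and 3 higher. The deleted means of Sit1 and Ttc30a1, 4.02 and 3.28, lie below the median of all probe set means, 4.29, so the size of these folds and their place in the order are uncertain. The rule fixed before the data were examined gave 30 named genes that passed over all genes, these 24 included. Of these 30 limma still called 10 with sex as a term. It called 0, 20 and 27 of them without floxed samples 1, 2 and 3, and 5, 15 and 17 without deleted samples 1, 2 and 3. The direction of all 30 stayed the same, but with no overlap between the groups leaving out a sample could not change it.

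**Figure D2:**
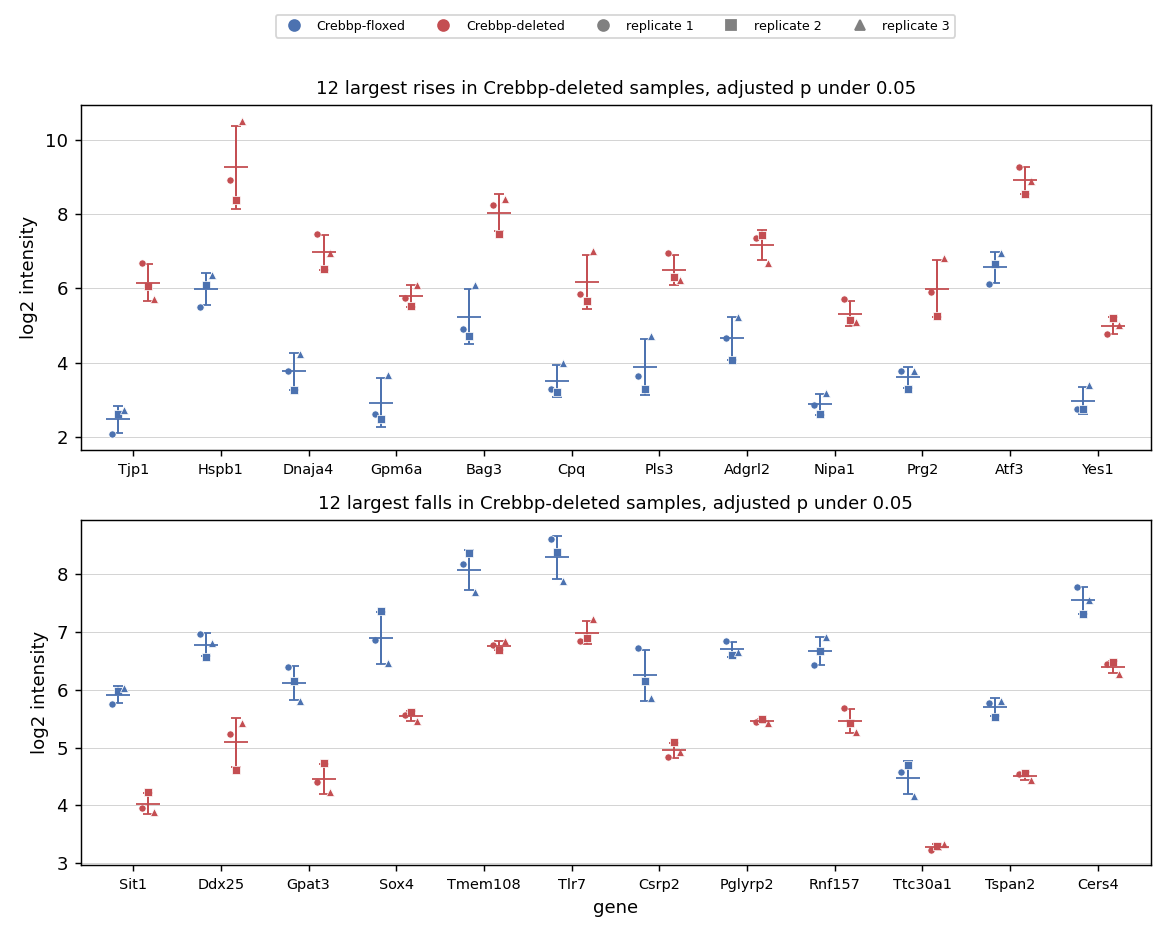
Log2 intensity in each of the 6 mice (points) for the 12 genes with the largest rise (top) and the 12 with the largest fall (bottom) among genes with an adjusted p under 0.05; lines and bars give the mean and SD of 3 samples. No deleted sample overlaps the floxed samples of the same gene, with Tjp1 12.8-fold higher and Sit1 3.72-fold lower.

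Plasma cell genes stood higher in the deleted samples. Of 13 measured members of the plasma cell list 1 rose over all genes tested and 10 rose when adjusted over the list alone, and 12 of the 13 differences were positive with a median of 1.33. Jchain, which joins the chains of polymeric IgM and IgA, rose from 11.06 ± 0.23 to 12.71 ± 0.24 (SD, n = 3 each; limma adjusted p = 0.011). Prdm1, the transcription factor that drives plasma cell differentiation, had a log2 difference of 1.88 (adjusted p = 0.073), the plasma cell surface proteoglycan Sdc1 one of 1.79 (adjusted p = 0.115) and the endoplasmic reticulum prolyl isomerase Fkbp11 one of 1.76 (adjusted p = 0.073). The list passed limma's camera test with its preset correlation (adjusted p = 2.6e-07) and did not pass with its own correlation (adjusted p = 0.407 with an estimated correlation). Deleted sample 3 had the highest mean score of the list, 1.85 above the floxed mean, against 0.71 and 0.92 in deleted samples 1 and 2, and without it the median was 0.75 (camera adjusted p = 9.04e-10). Of the 8 immunoglobulin heavy chain constant genes 3 were measured, too few for the set test, and 1 rose over all genes and 3 adjusted over the list alone. Ighm rose by 0.63 log2 units (limma adjusted p = 0.032), while Igha and Ighg3 stood 2.45 and 2.24 higher without passing (adjusted p = 0.099 and 0.326).

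Macrophage genes were higher in the same samples. Of 14 measured members of the monocyte and macrophage list 0 passed limma's test over all genes, 8 had an unadjusted p under 0.05, and 4 rose adjusted over the list alone. The median difference was 1.15. The complement genes C1qa, C1qb and C1qc, which tissue macrophages make, had log2 differences of 1.97, 2.09 and 2.11, and Cd5l, which splenic macrophages secrete, one of 1.59. The list passed camera (adjusted p = 6.32e-05) but not with its own correlation (adjusted p = 0.612 with an estimated correlation), and its mean score in floxed sample 1, 0.70, exceeded that of deleted sample 2, 0.58. The score also followed sex. It was 0.70, 1.20 and 1.58 in the males (floxed 1, deleted 1 and deleted 3). In the females (floxed 2, floxed 3 and deleted 2) it was −0.67, −0.04 and 0.58. With sex as a term the median difference was 0.83 (camera adjusted p = 8.46e-06), and without floxed sample 2 it was 0.86 (camera adjusted p = 0.00905). Markers of other cells did not pass camera with all samples. The median difference was 0.06 for the T cell list (camera adjusted p = 0.304), 0.02 for NK cells (0.907), 0.17 for neutrophils (0.637), 0.06 for dendritic cells (0.447), 0.19 for the erythroid list (0.657), −0.003 for megakaryocytes and platelets (0.948) and 0.09 for stroma and endothelium (0.709). In each of these 7 lists limma called 0 members, over all genes and adjusted over the list alone, and 0 to 2 members had an unadjusted p under 0.05. Without floxed sample 3 camera at its preset correlation passed 3 of the 7 upward: T cells (0.23, adjusted p = 0.0395), NK cells (0.28, adjusted p = 0.0043) and dendritic cells (0.41, adjusted p = 0.00346). With an estimated correlation there they did not pass (adjusted p = 0.509, 0.294 and 0.51).

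Heat shock genes rose together. All 11 measured members were higher in the deleted samples with a median difference of 1.39; 3 rose over all genes and 11 rose adjusted over the list alone. Those past the test over all genes were Hspb1, Bag3 and Hsph1, an Hsp110 chaperone that rose by 1.39 log2 units (limma adjusted p = 0.036), and the DnaJ chaperone Dnaja1 had a difference of 1.09 (adjusted p = 0.062). The list had the smallest p of all lists in camera (adjusted p = 2.69e-10), and did not pass with its own correlation (adjusted p = 0.313 with an estimated correlation). The mean score of the list was 1.32 to 1.91 in the deleted samples and 0.47 in floxed sample 2, the highest of the floxed ones. The list also passed fry, which tests whether the genes of a list move one way on balance (adjusted p = 0.038). Members of the unfolded protein response list were higher too, all 16 of them, with a median of 0.48. Of these 0 passed limma's test over all genes, 8 had an unadjusted p under 0.05 and 2 passed adjusted over the list alone. Asns, which makes asparagine, had a log2 difference of 2.32 (limma adjusted p = 0.068), Chac1 one of 1.11, Sdf2l1 one of 0.94 and Pdia4 one of 0.70. That list passed camera (adjusted p = 2.36e-05) and did not with its own correlation (adjusted p = 0.613 with an estimated correlation). Its mean score was 1.13 in deleted sample 3 and 0.35 and 0.34 in deleted samples 1 and 2, and without deleted sample 3 the median was 0.27 (camera adjusted p = 2.93e-05). The plasma cell list was also highest in deleted sample 3 (1.85, against 0.71 and 0.92). The 2 lists share no member, but whether they rose separately from each other was not tested.

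**Figure D3:**
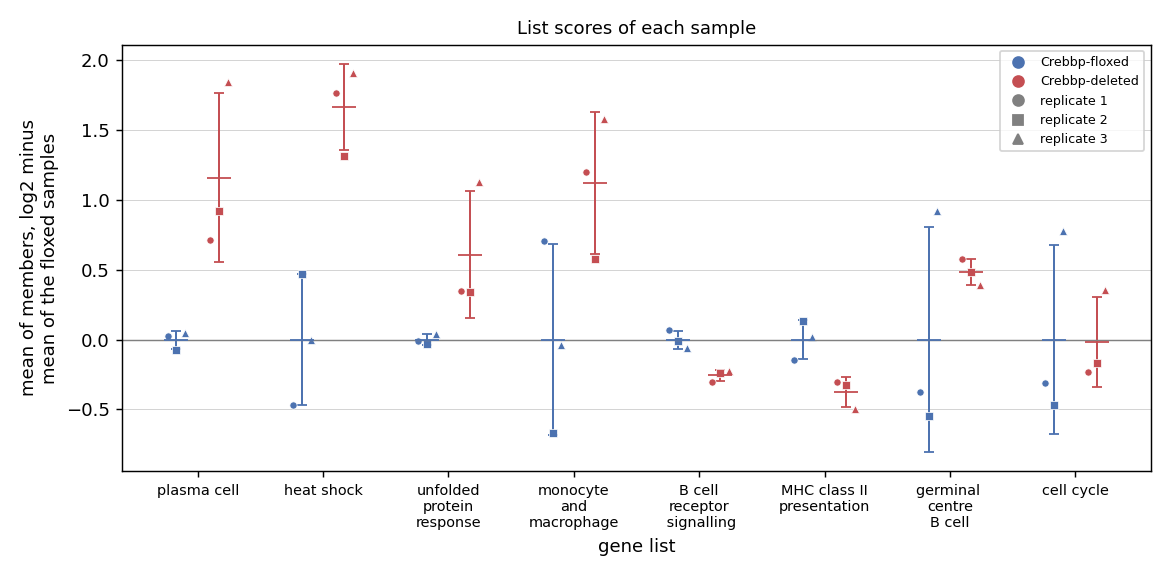
Mean over the members of 8 gene lists in each of the 6 mice (points), as log2 intensity minus the gene's mean in the floxed samples; lines and bars give the mean and SD of 3 samples. Plasma cell, heat shock and unfolded protein response scores of all deleted samples lie above all floxed samples, B cell receptor and MHC class II scores lie below, and floxed sample 3 has the highest germinal centre and cell cycle scores, 0.92 and 0.78.

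Most genes of B cell receptor signalling stood lower. Of 22 measured members 2 fell over all genes, and 4 fell and 1 rose adjusted over the list alone; 17 differences were negative, with a median of −0.23. Cd79a, the receptor's Igα chain, fell from 11.93 ± 0.14 to 10.82 ± 0.06 (SD, n = 3 each, limma adjusted p = 0.0093). The inhibitory co-receptor Cd72 fell by 1.04 log2 units (limma adjusted p = 0.020). Cd72 lies next to Sit1 in the gene order, and a linked segment from another strain, taken up below, was not excluded for this pair. The phosphatase Ptpn6 had a difference of −0.47 (adjusted p = 0.117) and the inhibitory Fc receptor Fcgr2b one of 0.44 (adjusted p = 0.151), with 1 of its 5 probe sets lower. The list passed camera (adjusted p = 6.63e-05) and fry (adjusted p = 0.006), and did not pass camera with an estimated correlation (adjusted p = 0.282). That estimate was −0.0195, below the preset 0.01, so correlation between its genes was not why it failed there. In the follicular B cell list 0 of 14 members passed limma's test over all genes and 6 had an unadjusted p under 0.05, and 4 fell and 2 rose adjusted over the list alone (median −0.22). The low-affinity IgE receptor Fcer2a, the homing receptor Cxcr5 and the inhibitory receptor Btla had log2 differences of −1.03, −0.57 and −0.67, and the quiescence factor Klf2 one of 0.68. Camera gave an adjusted p of 0.023 for it (adjusted p = 0.613 with an estimated correlation), which rose to 0.076 without floxed sample 2, 0.248 without deleted sample 3 (median −0.12), 0.108 with sex as a term and 0.082 with only genes above the median of probe sets.

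MHC class II genes were slightly lower. Of 11 measured members 0 passed limma's test over all genes, 7 had an unadjusted p under 0.05 and 6 fell adjusted over the list alone. Of the 11, 10 of the differences were negative, and the median was −0.30. The lowest, −0.91 in H2-Ea, came from floxed sample 2 alone, at 9.61 against 6.30 to 6.67 in the other 5 samples (a gene chosen after its values were seen), and without that sample the list median was −0.30. Among them H2-Oa, a modulator of peptide loading, had a difference of −0.52, the peptide-loading chaperone gene H2-DMb2 one of −0.37, and the classical chains H2-Ab1 and H2-Eb1 differences of −0.30 and −0.27; in each the deleted samples lay below the floxed ones. The list passed camera (adjusted p = 3.94e-05) and did not with its own correlation (adjusted p = 0.484 with an estimated correlation). Class II and follicular scores were lowest in deleted sample 3 (−0.50 and −0.43), which had the highest plasma cell and macrophage scores (1.85 and 1.58), whereas the B cell receptor score was lowest in deleted sample 1 (−0.30). Genes of precursor and immature B cells had a median of −0.24, with 1 of 13 members, Sox4, lower over all genes and 1 adjusted over the list alone. The early B cell gene Vpreb3 had a difference of −0.92, the transitional B cell marker Cd93 one of −1.02 (with 2 of its 5 probe sets higher and the groups overlapping) and the transcription factor Myb one of −0.53. Camera gave an adjusted p of 0.019 for this list (adjusted p = 0.343 with an estimated correlation). Its median was −0.044 without floxed sample 1, −0.14 without floxed sample 3 and −0.13 without deleted sample 2, and it passed in each (camera adjusted p = 0.0293, 0.00873 and 0.0426).

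Among NF-kB targets 0 of 15 members passed limma's test over all genes, 5 had an unadjusted p under 0.05 and 4 fell adjusted over the list alone (median −0.19). The pathway's own genes Nfkb2, Relb and Nfkbie and the signalling adaptor Traf1 had log2 differences of −0.44, −0.52, −0.49 and −0.77. Camera gave an adjusted p of 0.011 (adjusted p = 0.407 with an estimated correlation), and 0.141 without floxed sample 3, and the median was −0.29 without floxed sample 1. Among 18 DNA repair genes 0 passed limma's test over all genes, 3 had an unadjusted p under 0.05 and 1, Atr, fell adjusted over the list alone; 15 differences were negative and the median was −0.09. The damage kinase Atr, the polymerase Parp1, Nbn of the MRN complex and the ligase Lig4 had differences of −0.38, −0.41, −0.33 and −0.50 (camera adjusted p = 0.011; adjusted p = 0.343 with an estimated correlation). The list passed without each sample in turn, with medians of −0.20 without floxed sample 1, −0.16 without deleted sample 1, −0.050 without deleted sample 2 and −0.16 without deleted sample 3. Among 18 p53 targets 0 passed limma's test over all genes, 9 had an unadjusted p under 0.05, 3 rose and 1 fell adjusted over the list alone, and the median was 0.16. Ccng1, Zmat3 and the pro-apoptotic gene Pmaip1 had differences of 0.40, 0.50 and 1.08, while the kinase Plk2 had one of −1.27. Camera gave an adjusted p of 0.023 for the p53 list (adjusted p = 0.514 with an estimated correlation), 0.051 without floxed sample 1, 0.094 without deleted sample 1 and 0.082 with only genes above the median of probe sets.

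**Figure D4:**
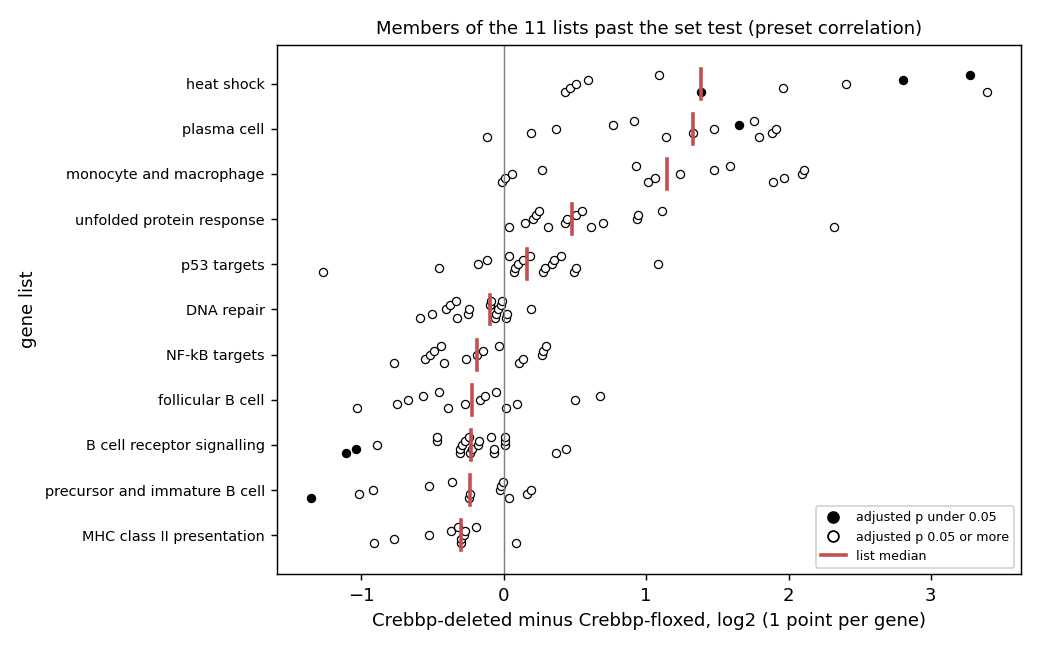
Log2 difference, deleted minus floxed, of every measured member (points) of the 11 lists with a camera adjusted p under 0.05 at the preset correlation; filled points are genes with an adjusted p under 0.05 over all genes, and vertical lines are list medians. Medians run from −0.30 for MHC class II to 1.39 for heat shock, and most members are not past the test on their own.

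The remaining lists did not pass camera with all samples. The germinal centre B cell list had a median of 0.54, with 0 of 12 members past limma's test over all genes, 2 at an unadjusted p under 0.05, and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.178; adjusted p = 0.931 with an estimated correlation). Its members Mef2c and Efnb1 had differences of −0.47 and 0.84. When each sample was left out in turn the list passed only without floxed sample 3, which had the highest score (median 1.06, camera adjusted p = 3.16e-09), and not with an estimated correlation there (adjusted p = 0.294). Without floxed samples 1 and 2 the medians were 0.33 and 0.15. Medians of the marginal zone, B-1, BCL6-repressed and interferon response lists were −0.15, 0.08, 0.33 and −0.33, with camera adjusted p of 0.331, 0.715, 0.304 and 0.279. Without floxed sample 3 the BCL6-repressed list passed upward (0.42, camera adjusted p = 0.00398) and the interferon list downward (−0.47, camera adjusted p = 0.00346), and without deleted sample 3 the marginal zone list passed downward (−0.33, camera adjusted p = 0.026). With an estimated correlation these 3 did not pass in the same settings (adjusted p = 0.294, 0.51 and 0.78). Without deleted sample 2 the median of the marginal zone list was 0.020 (camera adjusted p = 0.925). In limma 0 members of the marginal zone, B-1, BCL6-repressed and interferon lists passed over all genes, and 2, 3, 3 and 4 had an unadjusted p under 0.05. Adjusted over the list alone, the B-1 list had 2 higher, among them the scaffold gene Ahnak at 1.93 (1 of its 4 probe sets lower); the BCL6 list had Prdm1 higher and Atr lower; the interferon list had Gbp3 higher at 0.95 and Oasl1 lower at −1.18. In the list of CREB targets and immediate early genes 1 of 25 members, Atf3, rose over all genes and 2 adjusted over the list alone, the second being Klf6 at 0.89 (median 0.15, camera adjusted p = 0.447). Jun had a difference of 0.77 (limma adjusted p = 0.235), and 16 of the 25 differences were positive.

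The transcription factor Myc rose by 1.07 log2 units (limma adjusted p = 0.032), as the only member past the test of the list of MYC targets and ribosome biogenesis, over all genes and adjusted over the list alone. That list had a median of −0.01, a mean of 0.04 and a camera direction of down (adjusted p = 0.907), so that its mean differed in sign. The cell cycle list had a median of −0.01 (camera adjusted p = 0.331), with 0 of 29 members past limma's test over all genes or adjusted over the list alone and 1 at an unadjusted p under 0.05. Its direction depended on the sample left out: it passed upward without floxed sample 3 (0.30, camera adjusted p = 0.00166) and downward without floxed sample 1 (−0.20, camera adjusted p = 0.027), floxed sample 2 (−0.27, camera adjusted p = 0.00958) or deleted sample 3 (−0.21, camera adjusted p = 0.0303). With an estimated correlation it passed in none of these (adjusted p = 0.678, 0.917, 0.925 and 0.862 in the same order). Oxidative phosphorylation had a median and mean of 0.01 against a camera direction of down (adjusted p = 0.948), glycolysis a median of 0.05 (camera adjusted p = 0.447), cholesterol synthesis one of −0.06 (0.331) and MHC class I presentation one of 0.02 (0.83). Glycolysis passed upward without floxed sample 3 (0.13, camera adjusted p = 0.0141) and cholesterol synthesis downward without floxed sample 1 (−0.21, camera adjusted p = 0.00943), and neither did with an estimated correlation there (adjusted p = 0.51 and 0.798). In these 4 lists limma called 0 members either way, with 0, 1, 1 and 0 at an unadjusted p under 0.05. The list of histone acetyltransferases and deacetylases had a median of −0.04 (camera adjusted p = 0.239), with the acetyltransferase Kat5 at −0.41; 0 of 27 members passed limma's test either way and 4 had an unadjusted p under 0.05. In the BCL2 family the median was 0.08 (camera adjusted p = 0.331), with 0 of 14 members past limma's test over all genes, 4 at an unadjusted p under 0.05, and Bcl2 lower adjusted over the list alone. The sex-linked list had a median of 0.97 (camera adjusted p = 0.657), with 0 of 5 members past limma's test either way and 0 at an unadjusted p under 0.05.

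In all, 11 of 33 lists passed camera with its preset correlation of 0.01, 5 upward and 6 downward. None passed camera with an estimated correlation, where the smallest adjusted p was 0.282, and 2 passed fry. A higher correlation cannot be the reason for every list. The estimate lay below the preset 0.01 for B cell receptor signalling (−0.0195), precursor and immature B cells (−0.0034) and DNA repair (0.0076). With an estimated correlation camera takes its degrees of freedom from the few samples, and at the preset one from the genes. Without floxed sample 3 the count of lists past camera was 18 at the preset correlation and 0 with an estimated one. With only genes above the median of probe sets it was 9, and with sex as a term it was 10.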

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

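The fits with sex as a term and within each sex, and camera with an estimated correlation without each sample in turn, were chosen after seeing the data; all other settings were fixed before the data were examined. All 142 genes kept the direction of their difference in every setting in which they were measured and tested singly, and so did all 90 genes followed by name. For genes whose groups do not overlap, all 142 and many of the 90, leaving out or weighting samples could not reverse it. Nor could a term for sex or fits within each sex. Only another normalization or another choice of probe sets could have done so. Most of the 90 were also singled out by a large change or a small p, or after their values were seen. The number of genes past the threshold did move. It was 50 (23 higher, 27 lower) with only genes above the 75th percentile of probe sets, 291 (172 higher, 119 lower) with array weights, 449 (253 higher, 196 lower) at an adjusted p under 0.1, and 82 (59 higher, 23 lower) with a change of at least 1 log2 unit. With all probe sets tested one by one 74 were lower. Leaving out 1 sample at a time gave 0 to 226 genes, 0 to 172 of them higher and 0 to 65 lower, with 0 in limma without floxed sample 1 (1990 at an unadjusted p under 0.05). Fewer samples leave fewer degrees of freedom, but the differing counts were not traced further and the cause was not tested. With sex as a term 37 genes passed (27 higher, 10 lower), and limma called 0 within males and 0 within females (0 higher and 0 lower in each), with 1798 and 1237 at an unadjusted p under 0.05. In the other settings the count stayed from 116 to 186.

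The replicate numbers gave no clear sign of a pairing. Same-numbered samples deviated from their group means with correlations of 0.033, 0.104 and 0.006. Floxed sample 1 and deleted sample 3, both male, correlated best with each other (0.079), and every other sample did so with its own number. At 3 samples per group this cannot exclude a pairing. With the replicate block the count was 126 (91 higher), 80 of them among the 142.

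Crebbp, with 1435224_at as its representative, passed with the mean of its probe sets (−0.70, adjusted p = 0.039) and at the looser threshold of 0.1 (−0.50, adjusted p = 0.078), and did not pass elsewhere in the tests of 1 value per gene, with −0.45 to −0.57 when 1 sample was left out. Its probe set 1436983_at passed when all probe sets were tested one by one (adjusted p = 0.033). Over its alternatives the adjusted p ran from 0.039 to 0.706.

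Of the lists, 10 to 18 passed camera when 1 sample was left out. With only genes above the median of probe sets 9 passed (not the follicular B cell and p53 lists, camera adjusted p = 0.0821 each). With an estimated correlation 0 passed camera, and 0 without any of the samples in turn, while 2 passed fry. The cause was not tested further, but for the B cell receptor list it was not correlation between its genes, as given above. Some lists past camera kept their call while the median moved: precursor and immature B cells to −0.044, DNA repair to −0.20 and the NF-kB targets to −0.29 without floxed sample 1, DNA repair to −0.050 without deleted sample 2, and the plasma cell list to 0.75 and the unfolded protein response to 0.27 without deleted sample 3. With only genes above the median of probe sets precursor and immature B cells moved to −0.45. With the mean of a gene's probe sets DNA repair moved to −0.058. None of the 11 lists past camera reversed. In lists that had not passed, the direction of the set test reversed in the following settings. The numbers beside them are medians, whose sign need not follow the direction of the set test. With only genes above the median of probe sets oxidative phosphorylation had 0.011 and megakaryocyte and platelet 0.047. With the mean of a gene's probe sets MHC class I had 0.00050, oxidative phosphorylation 0.0012 and megakaryocyte and platelet −0.0028. With sex as a term megakaryocyte and platelet had 0.0043. In fry MYC targets had −0.011, oxidative phosphorylation 0.011 and megakaryocyte and platelet −0.0028. Leaving out 1 sample gave medians of −0.042 to 0.052 for oxidative phosphorylation, −0.094 to 0.053 for megakaryocyte and platelet, −0.041 to 0.12 for MHC class I, −0.069 to 0.045 for MYC targets, −0.045 to 0.28 for NK cell, −0.47 to 0.047 for interferon response, −0.028 to 0.13 for glycolysis, −0.21 to 0.099 for cholesterol synthesis, −0.13 to 0.40 for neutrophil, −0.16 to 0.41 for dendritic cell, −0.27 to 0.30 for cell cycle, 0.011 to 0.16 for CREB targets and −0.064 to 0.25 for erythroid. With an estimated correlation and 1 sample left out the following reversed. Without floxed sample 1 these were MYC targets (0.045), oxidative phosphorylation (0.052) and NK cell (−0.042). Without floxed sample 2 they were MHC class I (−0.0091), interferon response (0.047), glycolysis (−0.028), cholesterol synthesis (0.099), NK cell (−0.045), neutrophil (−0.0020), dendritic cell (−0.12) and megakaryocyte and platelet (0.053). Without floxed sample 3 they were cell cycle (0.30) and oxidative phosphorylation (0.031). Without deleted sample 1 they were CREB targets (0.011) and oxidative phosphorylation (0.019), and without deleted sample 2 MHC class I (−0.041), MYC targets (−0.0074) and NK cell (0.000011). Without deleted sample 3 they were NK cell (−0.012), neutrophil (−0.13), erythroid (−0.064) and megakaryocyte and platelet (−0.00045). The cause was not tested.

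The 6 samples can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. Of these 1, the real one, gave as many as 142 genes, and the highest of the others gave 3, in the division that follows sex. The real division was also the 1 of the 10 with as many as 99 genes in 1 direction (highest other 2) and the 1 with as many as 43 in the opposite one (highest other 2). For the lists, 7 of the 10, the real one included, gave 11 or more past camera, and the highest other gave 16, so the number of lists at the preset correlation did not set the real division apart.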

Other observations

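The tests in this part on other cell types, sex, immediate early genes and neighbouring genes were chosen after the results were seen, and so was the use of the planned fits without deleted sample 3 as tests of that sample alone. Floxed sample 3 stood apart from the other floxed samples in several lists. Its mean score was 0.92 in the germinal centre list, against −0.37 and −0.55 in floxed samples 1 and 2 and 0.39 to 0.58 in the deleted samples, and 0.78 in the cell cycle list, against −0.31 and −0.47 in the other floxed samples. It was also higher in the NK cell list, at 0.63 against −0.21 and −0.42, the dendritic cell list, at 0.65 against −0.08 and −0.57, the neutrophil list, at 0.55 against −0.06 and −0.49, and the T cell list, at 0.21 against 0.07 and −0.28. Without it the cell cycle list had a median of 0.30 (camera adjusted p = 0.00166, range over the alternatives 0.00166 to 0.985) and the germinal centre list one of 1.06 (camera adjusted p = 3.16e-09, range 3.16e-09 to 0.961), while the cell cycle list went the other way without floxed sample 2 (−0.27, camera adjusted p = 0.00958). With an estimated correlation neither passed in these settings (cell cycle 0.678 and 0.925, germinal centre 0.294). Floxed sample 2 stood alone in the class II gene H2-Ea, at 9.61 against 6.30 to 6.67 in the other 5 samples, and in the dynein gene Dnah8, at 6.88 against 3.91 to 4.13. The strain background of single mice was not analysed here. Both genes, and the following ones, were chosen after their values were seen. Among the light chain genes, Iglv1 rose by 1.78 and Igkv6-14 by 1.37 log2 units in the deleted samples. The receptors for polymeric immunoglobulin, Pigr, and for IgM, Fcmr, fell by 1.06 and 0.85.

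Plasma cell genes stood 1.33 higher (median) in the deleted samples although purification removes cells with CD43, which plasma cells and many myeloid cells carry. A lower share of B cells that let in every other cell type alike would be expected to raise other markers too. The median of 38 members of 7 other lists above the median of all probe sets was 0.091 (95% bootstrap interval 0.01 to 0.25), against an interval of 0.77 to 1.76 for the plasma cell list. Without floxed sample 3 it was 0.30 (0.12 to 0.45), against 0.86 to 1.63. These intervals resample the genes of a list, not the mice, so they do not measure the spread between mice. The comparison cannot exclude a lower share of B cells. Some of the 38 genes were already high in the floxed samples, such as Cst3 at 10.91 and Tfrc at 8.655, where a small carry-over adds little. Macrophage genes, which rose, were not among the 38. Deleted sample 3 alone does not account for the plasma cell rise, since deleted samples 1 and 2 scored 0.71 and 0.92, above all floxed samples. Without deleted sample 3 the list median was 0.75 (camera adjusted p = 9.04e-10, range over the alternatives 9.04e-10 to 0.882). Camera at its preset correlation sets the list against all other genes, so this p does not measure the spread between mice. The unequal sexes alone do not account for the plasma cell rise either. The floxed male scored 0.03, beside −0.07 and 0.05 in the floxed females. The deleted female scored 0.92, between the deleted males (0.71 and 1.85). With sex as a term the median was 1.20 (camera adjusted p = 4.48e-06). Within each sex every deleted sample scored above every floxed sample, but that follows from groups that do not overlap. With 1 floxed male and 1 deleted female a part played by sex is not excluded. The macrophage list, with an interval of 0.49 to 1.79, moved about as much, so a shared carry-over of plasma cells and macrophages stays open, as does more plasma cell differentiation in the deleted mice.

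Heat shock genes stood 1.39 higher (median) in the deleted samples. If more stress during thawing or handling were the cause, immediate early genes would be expected to rise with them, and Atf3 (2.33), Klf6 (0.89) and Jun (0.77) stood higher, but the list median was 0.15. That median decides little, because its members went both ways (16 positive and 9 negative). The 2 explanations, handling and a lasting difference between the genotypes, cannot be told apart for these genes. Deleted sample 3 alone does not account for the difference, since deleted samples 1 and 2 scored 1.77 and 1.32, above all floxed samples. Without deleted sample 3 the list median was 1.37 (camera adjusted p = 6.54e-10, range over the alternatives 1.8e-11 to 0.533). This p, too, does not measure the spread between mice.

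Some of the genes that differed lie next to each other. Of 141 such genes placed in the gene order of GRCm38.p6, 5 pairs were at most 2 places apart (Pigr and Fcmr, Tmtc3 and Cep290, Cd72 and Sit1, Trim5 and Trim12a, Thyn1 and Ncapd3), both genes of each pair moving the same way (with 1 of the 4 Tmtc3 probe sets lower), against a mean of 2.17 pairs in 10000 random sets (one-sided permutation p = 0.069). Linked chromosome segments from another strain may contribute, and this cannot be told apart from chance or from shared regulation at 5 pairs. A segment carried along with the deleted Crebbp gene stays open, since 1 of 36 measured neighbours of Crebbp differed (Coro7, −0.72). Windows around random genes held a mean of 0.392 such genes, and a share of 0.33 of those windows held as many. Those windows reached up to 25 genes to each side, so most were larger than the window of 36 genes around Crebbp.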
